A study of Mus musculus with 2 samples.

How the data were processed

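Lung tissue of 2 male B6CASTF1/J mice aged 36 days was profiled by DNase-seq, with 1 library per mouse. Both libraries form 1 group, per the labels, and carry the replicate numbers 1 and 2 given there. The labels name 2 numbered animals and give both the same donor entry, so replicates may share more than separate mice would, and p-values describe these libraries. The deposited descriptions state that all lists were made from filtered alignments to mm10, separately for each library and not on pooled reads. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here.

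For each library the authors deposited a rate of cutting per stretch of bases with its false discovery rate, an FDR, and listed only stretches up to 0.05. The highest listed was 0.0500 in replicate 1 and 0.0499 in replicate 2. The authors deposited 2 peak lists per library whose value is taken to be a signal scaled by depth. Within a library each value was a whole multiple of 1 step (100% of values within 0.05 of a step), which gives a depth ratio of 1.88 between replicate 2 and replicate 1 if a step stands for 1 cut. Only if the signal is a CPM-like rate do the steps stand for 93.8 M and 177 M cuts. Every peak of the strict lists touched bases with an FDR up to 0.001 (100% in each library), and every peak of the looser lists touched bases up to 0.05. The other value columns of the peak lists were empty. The deposited footprints carry 1 constant FDR level of 0.01, so they could not be ranked. A hybrid mouse carries a second genome that differs from mm10, and fewer of its reads may have aligned. Alleles were not analysed here.

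Coordinates are mm10, 1-based, as in the lists. Start sites, exons, introns and sequence came from the GRCm38 reference with the GENCODE M21 annotation, and 0 intervals of any list reached past a chromosome end. Peaks were compared with bedtools 2.31.1 and with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and pysam 0.24.0, and figures were drawn with Matplotlib 3.10.9. An overlap of at least 1 bp counted, and a shared peak is a merged interval that holds a peak of each library. The design had foreseen broad regions as the second list, and the looser list took that place. Footprint sharing was set against the share after a shift of 200 bp within shared peaks. Peak midpoints were put in promoters (1000 bp to each side of a protein-coding start site), coding exons, UTRs, introns or other sequence.

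A promoter was called open when a shared peak lay within 500 bp of any annotated start site of a protein-coding gene. Marker lists were fixed before the data were examined, as were the tests, the motifs and most alternatives. The 26 lists hold 308 genes, all found in the annotation: alveolar type 2, alveolar type 1, airway secretory, ciliated, endothelial, lung capillary, lymphatic endothelial, lung fibroblast, smooth muscle and pericyte, mesothelial, macrophage and monocyte, T and NK cell, B cell, neutrophil, cardiomyocyte, hepatocyte, neuron, skeletal muscle, nephron, pancreas, germ cell, intestine, constitutive, imprinted, anterior Hox and posterior Hox. Each list was compared with 100000 random gene lists of its size matched on deciles of promoter CpG content, in a two-sided permutation test with Benjamini-Hochberg adjustment at 0.05. Distal peaks were shared peaks within 25 kb of the most upstream start site and over 1 kb from every protein-coding start site. Their mean number per gene was tested in the same way, with lists matched on 5 classes of CpG content and on the number of neighbouring start sites. Anterior and posterior Hox genes were compared by Fisher's exact test.

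Matches of 31 consensus motifs were counted on both strands in footprints within strict peaks and in the rest of those peaks. The ratio of both rates was divided by the same ratio for the consensus written backwards, as a control for base composition. Written backwards, a consensus can lose or gain a CpG, so this does not control for CpG density. An exact two-sided sign test ran over chromosomes 1 to 19 and X in each library, and a motif was called when both libraries passed in the same direction, with the larger p adjusted over the motifs. Chromosomes without matches of the backwards consensus tied and dropped out.

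Named genes followed a rule. Of each list it took the 2 members with the highest mean percentile of their promoter peak value and the first 2 in alphabetical order without a peak in either library, and for lung lists also the member with most distal peaks. Of all genes it took the 5 with most distal peaks, and for each library the 3 strongest promoter peaks with none in the other. Other names, such as Sftpc, Nkx2-1, Lamp3, Cdh5, Emcn and the surfactant genes, were chosen after their values were seen.

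The steps were tested on simulated data. For shared peaks, 20000 intervals were simulated, part of them shared, and 100% of the shared ones were found. The simulated shifts were too small to undo an overlap, so this checks the counting only. For open promoters among 21938 genes, 85.5% of changed lists were called in the right direction and 0.182% of unchanged ones were called. The changed lists were made nearly all open or nearly all closed, so the 85.5% does not hold for smaller differences. For distal peaks, 43.0% of lists raised 2.4-fold were called against 0.250% of unchanged ones, so a distal excess of that size is missed more often than not. For the 31 motifs a median of 100% and at the lowest 99.5% of planted matches were found.

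The alternatives fixed at that time were a reciprocal overlap of 0.5, the stronger part of each list by value, lists of equal length, other promoter and distal windows, the looser lists, Fisher's exact test in place of matched draws, flanks of 100 bp as motif background and the peaks of either mouse alone. Added after seeing the data were footprints thinned at random, random positions as footprint background, start sites of the basic transcript set, draws matched on the number of start sites, looser and equal-length lists for some tests, a test of lists between the mice against 10000 random lists, a second B cell list and gene families. The peak value was compared between mice only at shared sites. A few single genes, a motif and a gene family that entered the counts are not reported here.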

Results

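DNase-seq maps accessible chromatin by sequencing where the nuclease DNase I cuts the DNA of nuclei. It was read here from lung tissue of 2 male mice of the B6CASTF1/J hybrid, the offspring of a laboratory strain and a wild-derived strain, both aged 36 days. The labels give 1 group, lung, with 1 library per mouse, named replicate 1 and replicate 2 after the labels. They describe 2 numbered animals but give both the same donor entry, so the spread between the libraries may be partly technical. Each library came with a strict list of peaks, which are stretches of dense cutting, a looser list, and footprints, which are short stretches inside accessible DNA that are protected from cutting. Replicate 1 held 77457 strict peaks, 125151 looser peaks and 229890 footprints, and replicate 2 held 138905, 200216 and 485196. The strict peaks had a median width of 185 bp and covered 14.2 Mb in replicate 1, and a median width of 200 bp and covered 26.9 Mb in replicate 2. The peak value is the authors' own signal and is taken to be scaled by depth. If its smallest step stands for 1 cut, which is an assumption, replicate 2 was 1.88 times as deep as replicate 1, and if it is a CPM-like rate as well, the libraries held 93.8 M and 177 M cuts. With 1 group there was no comparison between conditions, so the questions were which sites both mice shared, which genes they lay at and which sequence motifs their footprints covered. A peak means a strict peak unless it is called looser. Values are given for replicate 1 and then replicate 2, with no replicate check behind a difference between the mice.

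Sites that both mice shared included promoters of genes that every cell uses and of some genes that define lung cells. Rplp0, which encodes a protein of the large ribosomal subunit, had a promoter peak valued at 15.0 in replicate 1 and 22.5 in replicate 2, and Sftpc, which encodes a surfactant protein, had one at 4.01 and 4.79. Of the strict peaks of replicate 1, 94.98% overlapped a strict peak of replicate 2 by at least 1 bp, against 52.9% in the other direction. Both lists merged to 72986 intervals with a peak of each mouse, 3867 with replicate 1 alone and 65067 with replicate 2 alone, and 44.1% of the bases covered in either mouse were covered in both. Sharing followed the peak value. In replicate 2 it went from 9.62% in the lowest decile of the list to 99.7% in the highest, and in replicate 1 from 81.1% to 99.9%. When the list of replicate 2 was shortened by value to the length of the other, 77.7% of the replicate 1 peaks and 77.6% of the replicate 2 peaks were shared. The looser lists overlapped by 90.8% and 56.7%.

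**Figure D1:**
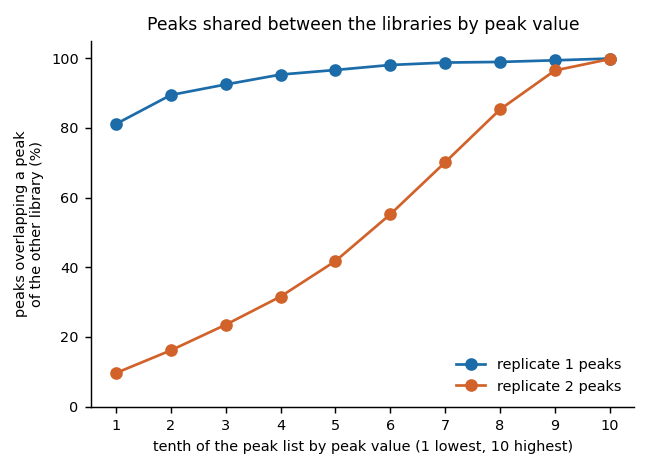
Share of the strict peaks of each library that overlap a strict peak of the other (vertical axis, percent) in deciles of that library's list ordered by peak value (horizontal axis, 1 lowest and 10 highest), with 1 point per library and decile. Replicate 1 lies between 81.1% and 99.9%, and replicate 2 climbs from 9.62% to 99.7%.

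At the 72986 shared sites the values of both mice followed each other, with a Spearman correlation of 0.92 and a Pearson correlation on the log10 scale of 0.95. Both are across sites, which are not independent replicates, so no p is given. The median log2 ratio of replicate 2 over replicate 1 was 0.33, with an SD of 0.45 across sites, and 95.6% of sites lay within 2-fold. Ratios over 4-fold were found at 13 sites higher in replicate 2 and at 0 sites higher in replicate 1.

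Some genes had a promoter peak in 1 mouse only. There were 33 such protein-coding genes in replicate 1 and 1415 in replicate 2. The strongest of replicate 1 were 4930442H23Rik, valued at 3.82 with no peak of either list in replicate 2, Gapdhs, the sperm form of the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, at 2.49, and Ptprcap, which encodes a partner of the lymphocyte phosphatase CD45, at 1.27 against a looser peak of 0.72 in replicate 2. Those of replicate 2 were Tbc1d10b at 22.7, the homeobox gene Six5 at 14.7 and Mamstr, a coactivator of muscle genes, at 6.49. The peak of Gapdhs and those of these 3 overlapped a peak of the other mouse whose edge fell outside the 500 bp window around the start site, so they do not mark sites closed in the other mouse. These cases are exceptions, since such an overlap was found for 4 of the 33 genes and 24 of the 1415.

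Promoters of protein-coding genes, counted as 1000 bp to each side of a start site, held far more peaks than their share of the genome. They took 28.9% of the peaks of replicate 1 and 22.3% of those of replicate 2, against 3.70% of the non-gap genome, which is 7.80 and 6.03 times that share. Introns held 32.5% and 37.1% of peaks against 34.0% of the genome. Coding exons held 1.04% and 1.38%, UTRs 1.36% and 1.58%, and all other sequence 36.2% and 37.6% against 60.1%. The shared peaks had a promoter share of 28.6%, and the replicate 2 peaks with no strict peak in replicate 1 had one of 15.2% with 42.1% in introns. These are shares with no test, each given for both libraries.

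The X chromosome carried fewer peaks than the autosomes in these male mice, which have a single X. It had 9.96 peaks per Mb of non-gap sequence in replicate 1 and 20.4 in replicate 2, against 31.6 and 56.6 on the autosomes, a ratio of 0.315 and 0.361. Chromosome 11 was the densest, with 48.1 and 83.0 peaks per Mb, and the Y chromosome held 19 and 30 peaks. Among peaks over 1 kb from every protein-coding start site, the X ratio was 0.276 and 0.344.

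Of 21938 protein-coding genes, 13133 (59.9%) had an open promoter, meaning a peak shared by both mice within 500 bp of an annotated start site. CpG-rich promoters were open far more often than CpG-poor ones, from 8.89% in the lowest decile by CpG content to 92.4% in the highest, so each gene list was set against random lists matched for it. Across the lists, 73 of 110 genes of lung cell types were open, 20 of 48 of blood cells, 10 of 95 of other organs and 22 of 24 controls. Of the 26 lists, 3 had more open promoters than matched draws, 7 had fewer and 16 did neither, by two-sided permutation tests with Benjamini-Hochberg adjustment, and 12 had an unadjusted p under 0.05. Genes are not independent replicates, so these p-values describe the 2 libraries.

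Among the lists with more open promoters, the strongest contrast was that of alveolar type 2 cells, the surfactant-making cells of the air sacs. All 12 of their genes were open, against 5.61 in matched draws (permutation test, adjusted p = 0.00026, the unadjusted 2e-05 being the smallest that 100000 draws can give). Etv5 (ENSMUSG00000013089.15), an ETS factor needed to keep type 2 cells, had the strongest promoter peak of the list, spanning its start site at chromosome 16, 22439681 to 22439920, with 22.6 and 26.7. Abca3 (ENSMUSG00000024130.16), the lipid transporter of lamellar bodies, followed with 8.27 and 13.5 at chromosome 17, 24351861 to 24352120. Nkx2-1, the lung and thyroid lineage factor, had 4.03 and 6.09, and Sftpb, Sftpa1 and Sftpd, which encode surfactant proteins, had 2.89 and 4.25, 2.33 and 3.52, and 1.33 and 1.80. The lowest of the list was Lamp3, a lamellar body membrane protein, with 1.17 and 1.33.

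**Figure D2:**
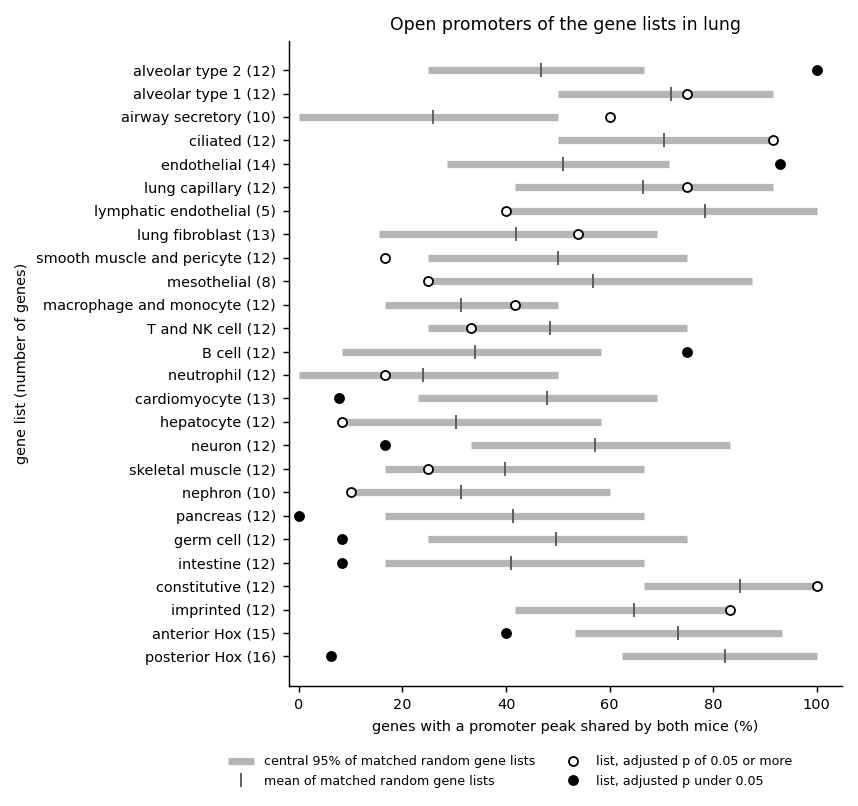
Share of the genes of each of the 26 lists with an open promoter (horizontal axis, percent), as 1 circle per list, filled where the adjusted permutation p is under 0.05, with the mean (tick) and central 95% (bar) of 100000 random lists matched on promoter CpG content. Alveolar type 2 (100%), endothelial (92.9%) and B cell (75%) lie above their bars, and 7 filled circles lie below theirs.

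**Figure D3:**
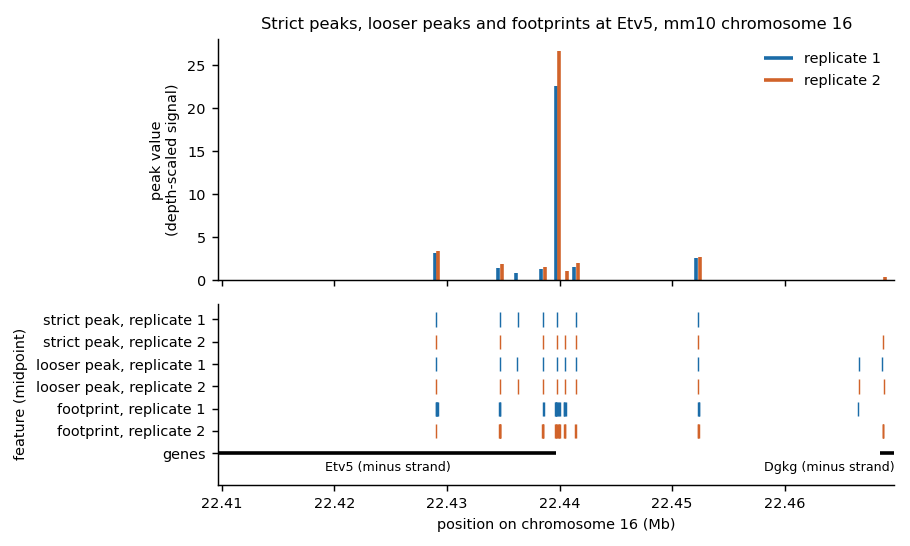
Map of the mm10 sequence 30 kb to each side of the Etv5 start site on chromosome 16 (horizontal axis, Mb). The upper panel gives the value of each strict peak per mouse (depth-scaled signal), with the promoter peak at 22.6 and 26.7, and the lower panel marks the midpoints of 7 and 8 strict peaks, 10 and 10 looser peaks and 26 and 29 footprints in replicates 1 and 2, with the genes Etv5 and Dgkg.

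Endothelial genes were open as a group. Of 14, 13 had an open promoter against 7.15 in matched draws (permutation test, adjusted p = 0.00354), the exception being Emcn, which encodes the vessel glycoprotein endomucin and had a peak in replicate 2 only, at 0.36. Tie1 (ENSMUSG00000033191.14), a receptor tyrosine kinase of vessels, had 5.09 and 6.41 at chromosome 4, 118489821 to 118490100, and Cldn5 (ENSMUSG00000041378.2), a tight junction claudin, had 4.30 and 5.80 at chromosome 16, 18776661 to 18776860. Cdh5, which encodes VE-cadherin, had 2.22 and 3.95. B cell genes were the third group, with 9 of 12 open against 4.09 (permutation test, adjusted p = 0.0114). Ebf1 (ENSMUSG00000057098.14) and Pax5 (ENSMUSG00000014030.15), which set and keep B cell identity, had 4.01 and 4.202 at chromosome 11, 44617141 to 44617360, and 3.41 and 3.15 at chromosome 4, 44704481 to 44704720. Of the genes of this list that were not open, Spib is an example. It had a looser peak in both mice, at 0.85 and 0.41, and with the looser lists all 12 genes of the list were open. All 3 groups were also called with the peaks of either mouse alone, and the B cell call alone was lost in Fisher's exact test against all other genes, which does not match for CpG content (adjusted p = 0.430).

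The other lung lists were not called against matched draws. Alveolar type 1 cells, which form the gas exchange surface, had 9 of 12 genes open against 8.62, with Rtkn2 at 3.30 and 3.63 and Hopx, a homeodomain-only factor, at 2.70 and 4.55. The 2 Hopx values belong to different peaks, each the highest near any of its start sites in that mouse. They lay at chromosome 5, 77095201 to 77095420 in replicate 1 and 77115181 to 77115380 in replicate 2, and each overlapped a peak of the other mouse. Ciliated cells had 11 of 12 against 8.46, led by Tppp3, a tubulin-binding protein, at 9.63 and 15.1 and Rsph1, a radial spoke protein, at 8.02 and 15.3, with the dynein gene Dnah5 as the exception. Airway secretory cells had 6 of 10 against 2.58 (permutation test, adjusted p = 0.0679), with Cyp2f2, a club cell cytochrome P450, at 1.87 and 1.87 and Aldh1a7 at 1.69 and 2.13, and no peak at Bpifa1 or Bpifb1. This list passed with the looser lists (7 of 10 against 3.12, permutation test, adjusted p = 0.0412) and, in alternatives chosen after seeing the data, with the basic transcript set (0.0491) and with draws matched on the number of start sites (0.00823), while it had 4 of 10 against 2.33 with lists of equal length (0.462) and 6 of 10 against 5.99 in Fisher's exact test. Lung capillary genes had 9 of 12 against 7.98, with the T-box gene Tbx3 at 5.49 and 9.26 and the BMP receptor gene Bmpr2 at 5.54 and 6.91. Lymphatic endothelial genes had 2 of 5 against 3.93, namely Lyve1, a hyaluronan receptor, and Prox1, the lymphatic master factor, with no peak at Mmrn1 or Reln. Lung fibroblast genes had 7 of 13 against 5.46, with Col1a1 at 2.80 and 4.88 and the growth factor receptor gene Pdgfra at 1.46 and 2.13, and no strict peak at Lum or Mfap4. Mfap4 had a looser peak in both mice, at 0.69 and 0.62. Mesothelial genes had 2 of 8 against 4.54, namely Aldh1a2 and Wt1, with no peak at Bnc1 or Gpm6a, and were lower with lists of equal length (1 of 8 against 4.38, permutation test, adjusted p = 0.0211), also chosen after seeing the data.

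Smooth muscle and pericyte genes had 2 of 12 open, Myh11, the smooth muscle myosin heavy chain, at 2.08 and 2.94 and Lmod1 at 0.62 and 1.21, against 6.00 in matched draws (permutation test, adjusted p = 0.0584). Cnn1 and Cox4i2 had no peak in either mouse. This list was lower with a 1 kb window (2 of 12 against 6.29, permutation test, adjusted p = 0.0390) and in Fisher's exact test (against 7.19, adjusted p = 0.0108), but had 6 of 12 against 6.81 with the looser lists, and 9 of 12 against 7.10 with replicate 2 alone, the library with more peaks. Among blood cells, macrophage and monocyte genes had 5 of 12 against 3.77, with the endosomal glycoprotein gene Cd68 at 3.50 and 3.33 and Cebpb, a myeloid leucine zipper factor, at 2.69 and 3.96, and no strict peak at the receptor genes Csf1r and Mrc1. Looser peaks lay in both mice at Csf1r (0.42 and 0.32) and at Mrc1 (0.55 and 0.32). The macrophage and monocyte list passed with replicate 2 alone (9 of 12 against 4.45, permutation test, adjusted p = 0.0161) and with the looser lists (10 of 12 against 4.31, adjusted p = 0.00199). T and NK cell genes had 4 of 12 against 5.83, with the kinase gene Lck at 3.04 and 5.34 and the adhesion gene Cd2 at 1.77 and 1.20, and no peak at Cd3d or Cd3e, which encode chains of the T cell receptor complex. Neutrophil genes had 2 of 12 against 2.87, Camp at 1.24 and 1.01 and S100a8 at 0.96 and 0.89, and no peak at Cebpe or Csf3r.

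Marker genes of other organs were mostly closed. Cardiomyocyte genes had 1 of 13 open against 6.24 (permutation test, adjusted p = 0.00354), neuron genes 2 of 12 against 6.87 (0.0109), pancreas genes 0 of 12 against 4.95 (0.00354), germ cell genes 1 of 12 against 5.96 (0.00797) and intestine genes 1 of 12 against 4.92 (0.0245). The open cardiomyocyte gene was Myl4 (ENSMUSG00000061086.12), the atrial light chain of myosin, with a peak spanning its start site at chromosome 11, 104550481 to 104550780, valued at 6.98 and 14.4, while Myh6 and Actc1 had no peak. The open germ cell gene was Dazl, an RNA-binding protein of germ cells, at 3.01 and 4.97, and the open intestine gene was Vil1, which encodes villin, at 0.83 and 0.92. The open neuron genes were Camk2a, a synaptic kinase gene, at 0.82 and 1.05 and Stmn2, a microtubule regulator gene, at 0.44 and 0.32. For both genes these values belong to different peaks in the 2 mice. Those of Camk2a lay at chromosome 18, 60963381 to 60963575 and 60963081 to 60963280, and those of Stmn2 at chromosome 3, 8509505 to 8509606 and 8509209 to 8509380. The Stmn2 peak of replicate 2 overlapped no peak of replicate 1, while the other 3 overlapped a peak of the other mouse. No peak in either mouse was found at Gad1 and Gad2, which encode the enzymes that make the transmitter GABA, at the digestive enzyme genes Cel and Cpa1, at Acr and Nobox of germ cells or at Alpi and Apoa4 of the gut lining. Hepatocyte genes had 1 of 12 against 3.64, with Alb at 0.46 and 0.42 and no peak at the plasma protein genes Ahsg and Apoa1, and nephron genes had 1 of 10 against 3.13, with the sodium chloride transporter gene Slc12a3 at 4.26 and 5.90 and no peak at the water channel gene Aqp2 or at Nphs1, which encodes nephrin. Skeletal muscle genes had 3 of 12 against 4.77, and the strongest, Mylpf, at 17.4 and 22.7, lies next to Tbc1d10b, with which it shares that peak, followed by the creatine kinase gene Ckm at 2.398 and 3.74, with no peak at Acta1 or Myf5. The neuron call was lost with a 1 kb window around start sites (permutation test, adjusted p = 0.150). The intestine call was lost with replicate 2 alone (0.182), with the looser lists (0.577) and with draws matched on the number of start sites (0.0686).

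As controls, all 12 constitutive genes were open against 10.2 in matched draws, with Rplp0 and the TATA-binding protein gene Tbp (13.2 and 16.6) the strongest. Imprinted genes had 10 of 12 open against 7.77, with Nnat at 5.85 and 7.97 and the cell cycle inhibitor gene Cdkn1c at 4.22 and 6.15, and with Igf2 and Dlk1 not open.

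Hox genes, the homeobox factors that lay out the body axis, were open more often at the anterior than at the posterior end of the clusters. Of 15 genes of paralogue groups 1 to 5, 6 were open, and of 16 of groups 9 to 13, 1 was open (Fisher's exact test, two-sided, p = 0.0373). The test treats each gene as independent, which neighbours in a cluster are not, so this p may be too small. With the looser lists, an alternative chosen after seeing the data, the difference fell from 33.75 to 27.5 percentage points, with 6 of 15 and 2 of 16 open, and did not pass (Fisher's exact test, p = 0.113). Among the open anterior genes were Hoxa4, Hoxb4 and Hoxb5. Hoxa5 (ENSMUSG00000038253.6), needed for normal lung development, was the strongest at chromosome 6, 52204401 to 52204620, with 5.08 and 6.79. The open posterior gene was Hoxa10 at 0.80 and 1.74. Hoxb3 and Hoxc4 among the anterior genes and Hoxa11 and Hoxa13 among the posterior ones had no peak in either mouse. Both groups were below matched draws, which expected 10.99 anterior and 13.2 posterior genes from their CpG content (permutation tests, adjusted p = 0.0154 and 0.00026). The anterior call was lost with replicate 2 alone, with 10 of 15 genes open (permutation test, adjusted p = 0.378), with draws matched on the number of start sites (0.107) and in Fisher's exact test against all other genes (0.178).

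Distal peaks, counted as shared peaks within 25 kb of a gene's most upstream start site and over 1 kb from every protein-coding start site, were most frequent around alveolar type 1 genes. These had 3.50 per gene against 1.47 around matched random genes (permutation test, adjusted p = 0.0328). Akap5, which anchors protein kinase A, had the most of that list, with 8, the strongest in an intron of the neighbouring Mthfd1 at chromosome 12, 76318801 to 76319160, with 2.75 and 2.17. Lung capillary genes had 3.25 against 1.59 and endothelial genes 2.86 against 1.39 (permutation test, adjusted p = 0.0619 for each). Constitutive control genes had 2.83 against 1.69 (permutation test, adjusted p = 0.123). A number near that of endothelial genes was thus not particular to lung lists. Of the 26 lists, 1 passed, 10 had an unadjusted p under 0.05 and 18 lay above their expected number. Skeletal muscle genes, with 0.83 per gene against 1.41, and neuron genes, with 0.92 against 1.496, had the fewest per gene and lay below it. With replicate 2 alone skeletal muscle genes lay slightly above it, with 2.92 against 2.78, while neuron genes stayed below, with 2.00 against 3.03. With replicate 2 alone 7 lists passed, namely alveolar type 2, alveolar type 1, airway secretory, endothelial, lung capillary, smooth muscle and pericyte, and macrophage and monocyte. With the looser lists 7 passed as well, with ciliated in place of smooth muscle and pericyte.

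Some lung genes without a shared promoter peak had distal ones. Cox4i2, a cytochrome oxidase subunit of pericytes, had no promoter peak in either mouse and 9 distal peaks, the strongest 18.97 kb upstream in intergenic sequence at chromosome 2, 152735101 to 152735300, with 8.14 and 12.6. The start site of 1 other protein-coding gene also lay within 25 kb, so these peaks cannot be assigned to Cox4i2. Scgb1a1, the secretoglobin of club cells, had a strict promoter peak in replicate 2 only, but looser ones in both mice, at 1.26 and 1.39. It had 8 distal peaks, the strongest in an intron of Ahnak at chromosome 19, 9071521 to 9071800, with 3.90 and 5.55. The mesothelial gene Upk1b, with a strict promoter peak in replicate 2 only and looser ones in both mice (0.49 and 0.46), had 3 distal peaks. Among genes with an open promoter, Sox18, an endothelial transcription factor, had 6, Sec14l3 of ciliated cells 6 and Bmpr2 6. Col1a1, which encodes a chain of type I collagen, had 5, with the strongest 22.02 kb downstream of its start site at chromosome 11, 94958121 to 94958360, at 4.56 and 5.79. Lyve1 had 4. Etv5 also had 5, with the strongest in its own intron at chromosome 16, 22428941 to 22429200, at 3.13 and 3.46. Over all protein-coding genes, Btg2, an antiproliferative gene, and Kdm6b, a histone demethylase gene, had the most, with 16 each, followed by Zfp36l1 with 15 and Borcs6 and Cyb5d1 with 14. The strongest at Btg2 lay at chromosome 1, 134060861 to 134061100, with 12.4 and 14.8. Kdm6b and Cyb5d1 are neighbours and share peaks, including one at chromosome 11, 69418821 to 69419140, with 9.59 and 13.3. Other protein-coding genes also had a start site within 25 kb of Lyve1 (1 gene), Borcs6 (2), and Sox18, Kdm6b and Cyb5d1 (3 each). Distal peaks were counted by distance alone, so those of such genes may lie closer to a neighbour.

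**Figure D4:**
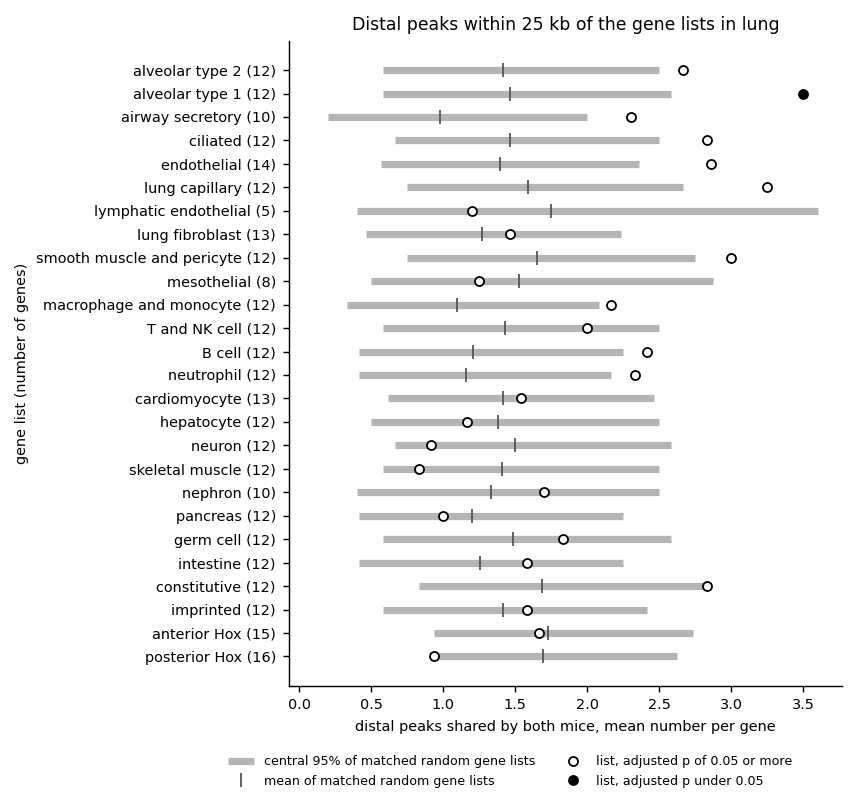
Mean number per gene of distal peaks shared by both mice (horizontal axis) for each of the 26 lists, as 1 circle per list, filled where the adjusted permutation p is under 0.05, with the mean (tick) and central 95% (bar) of 100000 matched random lists. Only the circle of alveolar type 1 genes, at 3.50 peaks per gene against 1.47, is filled.

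Footprints lay mostly inside the strict peaks, with 75.9% of those of replicate 1 and 75.6% of those of replicate 2, and 86.2% and 89.2% of strict peaks held at least 1. Their median width was 10 bp. Of the footprints of replicate 1, 66.1% overlapped a footprint of replicate 2, and of those of replicate 2, 29.4% overlapped one of replicate 1. Within shared peaks the shares were 70.6% and 48.4%, against 35.5% and 22.5% after a shift of 200 bp for the footprints that stayed inside such a peak. Against footprints placed at random in the same peaks, a background chosen after seeing the data, they compared with 44.1% and 32.1%. With the longer list thinned at random to the length of the shorter, 31.9% and 29.5% overlapped.

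Binding motifs found in the footprints of both mice included those of factors that act in lung, those of general promoter factors and the neuronal E-box. The consensus of NKX2-1, the lung lineage factor, matched 2.82 and 5.17 times as often in footprints as in the rest of the same peaks, relative to the same consensus written backwards, and was higher on 20 of 20 chromosomes in each mouse (exact sign test, adjusted p = 1.18e-05). ETS sites with a CpG, the class of Etv5 and other ETS factors, were at 4.71 and 5.74, and SOX sites at 3.06 and 2.70 (20 of 20 chromosomes in each mouse, exact sign test, adjusted p = 1.18e-05 for both). ETS sites without a CpG, at 3.30 and 1.62, were not called (exact sign test, adjusted p = 0.0802), and their matches were less dense in footprints than in the rest of the peaks, at 0.856 and 0.814 times. The cyclic AMP response element CRE reached 22.3 and 26.2 on 20 of 20 chromosomes. Written backwards, the consensus of ETS sites with a CpG, of CRE and of the USF E-box holds no CpG. Their ratios therefore do not separate the motif from the density of CpG in footprints. CTCF, the factor that shapes chromatin loops, was at 6.75 and 34.8, higher on 12 and lower on 2 chromosomes in replicate 1 and 16 against 1 in replicate 2 (exact sign test, adjusted p = 0.0267). Its consensus written backwards always holds a CpG that the consensus itself need not hold, so the CTCF ratio is not matched for CpG either. Of the 31 motifs 14 were higher in footprints in both mice, 1 was lower and 16 were neither, with 16 at an unadjusted p under 0.05. The others that were higher were AP-1, TEAD, CEBP, GATA, RUNX, NFY, the E-box of USF, ZNF143 and the neuronal E-box. The neuronal E-box was at 5.08 and 4.51, on 20 of 20 chromosomes in each mouse (exact sign test, adjusted p = 1.18e-05). High ratios were thus not particular to factors of lung. AP-1, TEAD, GATA, RUNX and SOX matches were less dense in footprints than in the rest of the peaks (AP-1 at 0.787 and 0.796 times), and were higher only relative to the backwards consensus, which was rarer still (AP-1 at 1.30 and 1.21).

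FOXA, the motif of the forkhead factors of lung epithelium, was the motif that was lower, at 0.525 and 0.439, on 17 of 20 and 20 of 20 chromosomes (exact sign test, adjusted p = 0.00666). PU.1, the factor of macrophages and B cells, was at 1.88 and 1.45 and passed in replicate 1 only, with matches less dense in footprints than in the rest of the peaks (0.657 and 0.615 times). The consensus of KLF and SP reads the same backwards, so its ratio is 1 by construction, although its matches were 11.6 and 16.3 times as dense in footprints as in the rest of the peaks. REST, NRF1 and HNF1 had too few backwards matches for a ratio in both mice. The CTCF call was lost with 100 bp flanks of the footprints as background (exact sign test, adjusted p = 0.0747), where the ratios stayed at 6.89 and 32.4, with 10 chromosomes higher and 2 lower in replicate 1 against 12 and 2 in the main comparison.

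**Figure D5:**
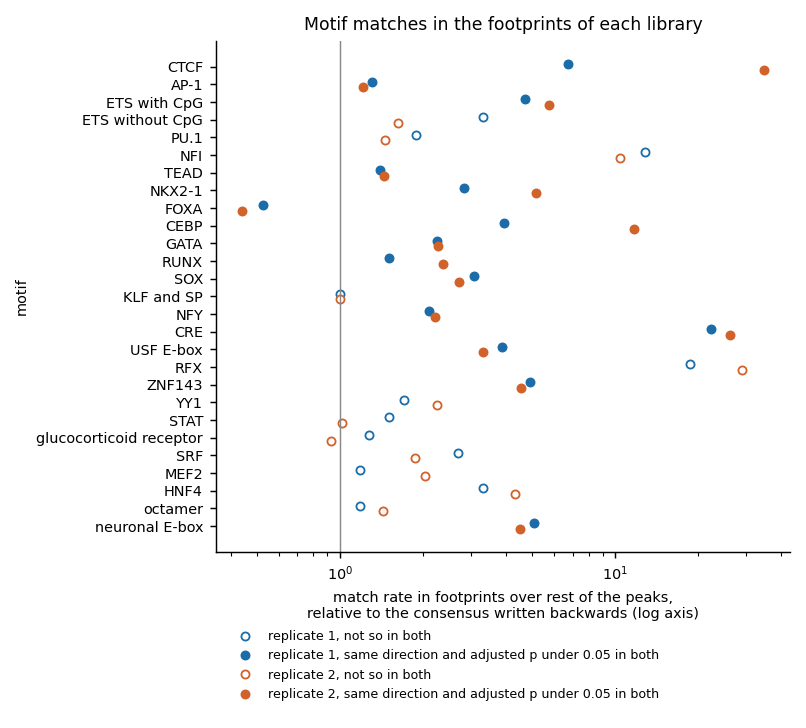
Match rate of each motif in footprints over that in the rest of the same peaks, divided by the same ratio for the consensus written backwards (horizontal log axis, 1 point per motif and library), for the motifs with a ratio in both libraries. Filled points mark the 14 motifs that lie above 1 and the 1 (FOXA, at 0.525 and 0.439) that lies below in both, and CTCF in replicate 2 is the highest at 34.8.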

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

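The tests of the peak lists and footprints here were set before their results were seen, and the share of accessible bases near peaks was added afterwards. Footprints outside both peak lists of their own library numbered 18392 of 229890 in replicate 1 and 55497 of 485196 in replicate 2. They were flagged because the motif comparison within peaks left them out, although the sharing of footprints between the mice counted them. The motifs that were higher in footprints within peaks were counted in these as well. Their median ratio over the backwards consensus was 3.42 for 12 motifs in replicate 1 and 2.60 for 13 motifs in replicate 2. Both passed the bound set beforehand against the idea that these footprints mark no protein. The ratios do not decide it, however. The motifs were chosen from footprints of the same libraries, so a preference of the calls for certain sequences, such as CpG, could raise both sets. A higher ratio did not hold for each motif: ETS sites with a CpG were at 10.8 and 9.05, with 17 and 20 chromosomes higher and 0 lower, while AP-1 was at 1.27 and 1.0006. AP-1, TEAD, GATA, RUNX and SOX had an unadjusted p over 0.05 in both mice (exact sign tests) and were less dense in these footprints than around them (AP-1 at 0.822 and 0.678 times). Whether they lie on flanks that the peak lists trim cannot be told, since 99.6% and 98.95% lay within 250 bp of a looser peak, but so did 97.8% and 96.6% of all bases up to an FDR of 0.05, and 99.70% and 99.79% of these footprints touched such bases. Of these footprints, 69.3% in replicate 1 and 19.3% in replicate 2 overlapped a footprint of the other mouse. With 1 group, no biological explanation was tested.

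Replicate 2 had 65378 strict peaks with no strict peak in replicate 1, against 3886 the other way. A candidate explanation is greater depth, put at 1.88 times by the step of the peak values if a step stands for 1 cut, and not measured otherwise: 80.2% of them lay in the weaker part of its list below the median, barely past the 80% set for it before the result was seen, and 52.2% touched bases up to an FDR of 0.05 in replicate 1. The others may be fainter still or absent in that mouse, which these lists do not separate. The replicate 1 peaks without a partner were weak as well, with 89.8% in the weaker part of its list. Unshared peaks were thus weak in either library, so this measure does not separate depth from other causes. No biological explanation was tested, since the design gives no group that separates the mice.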

How the results depend on the processing

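Tests added after the results were seen were thinned footprints, random footprint positions, the basic transcript set, start-site matching, and looser or equal-length lists for some results. No call on a list or motif turned into the opposite call. Some lists without a call in the main comparison did cross their expected number. With replicate 2 alone, open smooth muscle and pericyte genes went from 2 against 6.00 to 9 against 7.10. Distal peaks per skeletal muscle gene went from 0.83 against 1.41 to 2.92 against 2.78 there. Those per hepatocyte gene went from 1.17 against 1.38 to 3.67 against 2.79 with a 50 kb window. Of 60 alternative values of the comparisons, 49 stayed the same and 10 moved. The Hox difference with looser lists (27.5 percentage points) was the 1 that was weaker. The cause was not tested unless stated. Thinned footprints of replicate 1 overlapped by 31.9%, from the thinning itself. Promoter shares were 24.02% and 17.2% with a 500 bp promoter, which covers less, and 41.5% and 30.8% in the part of each list above its median value. The X ratio of replicate 1 was 0.276 for distal peaks. With looser lists 5 gene lists had more open promoters, the 3 called before among them. With Fisher's exact test 11 had fewer, 6 of the 7 called before among them. Distal peaks were higher around 7 lists with looser peaks. With 1 mouse left out in turn, lists with more open promoters numbered 3 to 4 and with fewer 5 to 7, lists with more distal peaks 1 to 7, with 7 from replicate 2 alone, motifs that were higher 17 in each and lower 1, and the Hox difference was 33.75 to 47.9 percentage points. Of 208 single calls on open promoters 187 stayed, 13 were gained and 8 lost, of 156 on distal peaks 144 stayed and 12 were gained, and of 81 on motifs 74 stayed, 6 were gained and 1 (CTCF) was lost. All 3 lists with more open promoters kept their call when draws were matched on start sites, which argues against start-site number as the only cause. A part played by it is not excluded. Matching raised the expected number from 7.15 to 8.60 for endothelial genes (permutation test, adjusted p = 0.0328) and from 4.09 to 5.15 for B cell genes (0.0288). For alveolar type 2 genes it went from 5.61 to 5.72. Of 600 values each for named promoters and distal counts, 28 and 180 moved. Ranking footprints by value could not be run, since their value is constant. No paired analysis was possible because there is 1 group. Of the peaks of replicate 2 alone, 45.9% had a looser peak in replicate 1.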

Other observations

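All tests of gene families and of lists between the mice were chosen after the peaks were seen, and the trend and GC tests of the B cell list after its result. Gene families differed in how often their promoters had a shared peak. Draws were matched on CpG content alone. How well reads map to genes of similar sequence was not checked, so a missing peak need not mean closed chromatin. Genes of a family that lie side by side are not independent, so the p-values describe these 2 libraries and may be too small. Of 30 families, defined by name patterns that were corrected once after a first run, 4 had more open promoters than 100000 draws matched on CpG content and 10 had fewer (two-sided permutation tests, Benjamini-Hochberg adjustment). Receptors of smell were rarely called open, with 7 of 1135 olfactory receptor genes against 176 expected and 1 of 329 vomeronasal receptor genes against 47.3 (permutation test, adjusted p = 0.0001 for both, from the smallest p the draws can give). Glutamate receptor genes, which serve synapses, had 1 of 26 against 17.5, namely Grik4, protocadherin genes 13 of 69 against 47.2 and potassium channel genes 37 of 94 against 58.2 (0.0001 each). Keratin-associated genes had 0 of 57 against 13.9 (0.0001), keratin genes 10 of 53 against 22.6 (0.000771), beta defensin genes 1 of 42 against 8.67 (0.00234), forkhead genes 24 of 44 against 34.0 (0.000933) and T-box genes 5 of 16 against 9.78 (0.0233). T-box genes that were open were led by Tbx3 and Tbx2, with values of 5.49 and 3.58 in replicate 1.

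Among the families with more open promoters were the ribosomal proteins, with 77 of 80 against 67.5 (permutation test, adjusted p = 0.000933), GATA and ETS factors, with 24 of 27 against 17.4 (0.00376), and proteasome subunits, with 38 of 40 against 31.7 (0.0113). Among GATA and ETS genes Etv5 was the strongest, followed by Ets1, an endothelial and lymphocyte factor, at 8.005 and 13.5 and Gata6, a factor of lung epithelium, at 6.58 and 8.04. Neither more nor fewer held for 16 families, among them claudins with 11 of 33, collagens with 21 of 44, cytochromes P450 with 27 of 100, chemokines with 10 of 35 and Toll-like receptors with 6 of 12. The interleukin receptors, with 25 of 40 against 18.5 (permutation test, adjusted p = 0.0525), and the subunits of NADH dehydrogenase, with 35 of 37 against 30.5 (0.0782), had passed with the first patterns, which caught genes outside those families.

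Values at shared looser peaks within 25 kb of the genes of 22 cell type lists were compared between the mice, as a description of 2 libraries with no replicate check. Before any correction 2 lists lay outside the central 95% of 10000 random lists, macrophage and monocyte (median log2 ratio of replicate 2 over 1, -0.20) and B cell (-0.30). After the trend with peak value was removed 3 did, with airway secretory (-0.17) added, and after that with value and GC content 2 did, endothelial (-0.14) and B cell, all of them higher in replicate 1. Since about 1 list in 20 falls outside by chance, these counts do not decide whether a value-dependent trend or the GC content of the sites accounts for the differences of the cell type lists.

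The B cell list was the lowest. Its median log2 ratio was -0.31 after the trend with value and -0.37 after that with value and GC content, where the lowest 2.5% of random lists began at -0.14, 0 of 10000 were as low and 12 of 12 genes lay below 0. Ms4a1, which encodes the B cell antigen CD20, had -1.23 before correction, Pax5 -0.81 and Cr2, a complement receptor, -0.70, while Ebf1 (0.03) and Spib (0.13) did not go that way. The medians after correction argue against both trends, and 12 of 12 genes below 0 argue against a single gene as the cause. With 1 gene left out the highest median was -0.36. That test could not decide the point, since dropping 1 of 12 genes barely moves a median. By rank among shared peaks the B cell list was lower in replicate 2 too (median difference -7.03 percentile points). A smaller share of B cells in the lung piece of replicate 2 may be behind it: a second B cell list with no gene of the first had -0.40, with 12 of 14 genes below 0 and 0 of 10000 random lists as low, while the T and NK cell list (-0.14, with a lower bound of -0.153) and the macrophage and monocyte list (-0.13, with one of -0.140) leaned the same way but stayed inside their central 95%. The neutrophil list (0.02) did not lean so, while the endothelial (-0.14) and airway secretory (-0.13) lists leaned as far as those of T cells and macrophages, so a shift of blood cells in general is not shown. Lymphoid tissue or blood carried along was not separated from it, and since the design gives no group for it, the reading stays a hypothesis on single mice.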
